A study of Mus musculus with 4 samples.

How the data were processed

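Gene expression was measured on 4 Affymetrix oligonucleotide arrays, 1 for each of 2 metastatic and 2 non-metastatic preparations of podoplanin-selected cells from tumour-draining mouse lymph nodes. Per the labels' protocols, 3 ug of total RNA was labelled with biotin in a single amplification cycle, and 20 ug of labelled cRNA was fragmented for hybridization. The values deposited by the authors are a log2 signal per probe set, as their range shows (3.10 to 14.87 over all arrays, with array medians of 5.88, 5.99, 5.96 and 5.98). The scale was read from the values and no centring was seen. The software that summarised the probes, and any normalization between arrays, are not given in the sources used here. No detection calls or scanner files were used here, so dim probe sets cannot be called absent. The number of arrays limits the precision.

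Groups were taken from the sample titles, which call the preparations biological replicates. A rule set before the data were examined asked for quantile normalization if the array medians differed by more than 0.1 log2 units. They differed by 0.116, so the 4 arrays were quantile normalized with limma, and the deposited log2 values served as an alternative. Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested, without a filter on dim ones. In the platform annotation used here 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Symbols were updated through Entrez gene numbers, which were found for 34741 of the single-gene probe sets. A gene was represented by its probe set with the highest mean over all 4 arrays, which gave 18193 genes. Probe sets of 1 gene can disagree, and the text says where those of a named gene that passed did. Some named genes (Aldoa, Cxcl1, Fgfr1, Lyz1, Mcm2, Notch3, Rrm2, Vegfd and Vldlr) are represented by probe sets that the array's naming marks as able to bind several transcripts.

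The comparison was fitted with limma (lmFit and eBayes) as metastatic minus non-metastatic, with 2 residual degrees of freedom, 3.71 prior degrees of freedom and a prior SD of 0.131 log2 units. A p was adjusted by Benjamini-Hochberg over all probe sets and called under 0.05. In the text, rose and fell are used of list members that passed after adjustment over their list alone. Gene list tests used camera over 1 probe set per gene with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 24 lists. Beside it stand camera with an estimated correlation and fry. With an estimated correlation camera's test has only the 2 residual degrees of freedom. A call lost there can reflect these as well as correlated members. With the preset correlation camera compares genes with other genes, so its p does not measure the variation between preparations. The lists were fixed before the data were examined and held 385 distinct genes, of which 366 were measured here. Named genes were Bmp4, Pdpn, Prox1, Lyve1, Flt4, Kdr, Pecam1, Cdh5 and Ptprc, the 12 genes with the largest difference in each direction, and up to 4 members of each list with the smallest p. As no gene passed, the 12 were taken by size among genes whose groups did not overlap. The text says where a gene was named outside this rule.

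The scripts were tested on simulated data with known changes on 45037 probe sets. They called 32.8% of changes of 1 log2 unit, 95.5% of changes of 2 and 100% of changes of 3, along with 10 unchanged probe sets. The noise came from limma's own fitted prior, without shifts shared by many genes of a preparation. These shares therefore check the scripts and do not measure what the real arrays can detect. On the real arrays Folh1, with a difference of -3.14, was not called (limma adjusted p = 0.266). With no list changed, 0 of 24 lists were called, and with 1 list shifted by -0.5, 1 was. Probe sets were simulated as independent of each other. The list test was therefore not tried on correlated members, such as those of the hypoxia and glycolysis list (estimated correlation 0.963). Alternatives fixed in advance were the deposited values, centring of array medians, the brighter probe sets only, the mean of a gene's probe sets, moderation with an intensity trend and robust settings, the replicate number as a block, a fold change of at least 2, an estimated inter-gene correlation, and each array left out in turn. The alternative pseudocounts were not run because the values are logs. The counts of list members without each array were added after seeing the data. A fit without 1 array has 1 residual degree of freedom and assumes that the lone array of a group varies like the other group. The lists' shifts between the replicates of 1 group were set against 10000 random lists of the same size, matched on mean signal, as a description of those arrays. R 4.3.3 with limma 3.58.1 was used for the statistics, and Python 3.11.15 with matplotlib 3.10.9 for the plots.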

Results

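The data describe cells taken from lymph nodes that drained tumours in mice. Tumours were grown under the skin of female immunodeficient SCID/NOD mice from human 293 cells, an embryonic kidney line. The 293-VEGF-D cells overexpress VEGF-D, a growth factor for lymphatic vessels, and form the tumours called metastatic in the labels, while 293-Apex cells form the non-metastatic ones. The draining axillary node was taken after 3 to 4 weeks, at tumour volumes of 1600 to 2500 mm3, and nodes of 1 to 5 mice were pooled for each preparation. Nodes draining metastatic tumours entered only if visibly enlarged. The digested cells were cultured briefly in medium for endothelial cells and then selected with magnetic beads for podoplanin, a surface protein of lymphatic endothelium that fibroblastic reticular cells of lymph nodes also carry. Each group had 2 biological replicates, 1 array each, so 4 arrays were compared. The sorting label states that tumour cells and leukocytes were depleted before culture for the metastatic preparations and that they were not for the non-metastatic ones, whereas the growth protocol describes the depletion without separating the groups. By the sorting label, the depletion therefore differs together with the group. VEGF-D overexpression by the tumour cells and the choice of visibly enlarged nodes also go with the group. None of these can be told apart from metastasis here. The number of arrays limits the precision of every value below.

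The comparison asks which genes differ between stromal and endothelial cells of nodes draining metastatic and non-metastatic tumours. Bmp4, a secreted growth factor of the bone morphogenetic protein family, had the smallest p of the 45037 probe sets. Its log2 signal was 6.78 ± 0.17 in the metastatic group and 9.43 ± 0.21 in the non-metastatic group (mean ± SD, n = 2 each), a difference of -2.65 (SE 0.16), or 6.30-fold lower signal. Scel, which encodes sciellin of the cornified envelope, differed by -2.59 (SE 0.16). Among the 12 genes with the most negative differences were the myosin light chain kinase gene Mylk at -3.07 (SE 0.34) and Ppp1r14a, an inhibitor of myosin phosphatase, at -2.23 (SE 0.30). The vessel genes Lyve1, a hyaluronan receptor of lymphatic endothelium, and Emcn, an endothelial sialomucin, stood at -2.76 (SE 0.64) and -2.53 (SE 0.29). The peptidase gene Folh1 had the most negative value, -3.14 (SE 0.45). The others were Lyz1 at -2.69 (SE 0.65), the desmosome gene Perp at -2.64 (SE 0.20), Serpinb6b at -2.59 (SE 0.33), the late cornified envelope gene Lce1f at -2.54 (SE 0.89) and the microtubule-associated gene Map2 at -2.43 (SE 0.47). Lyz1 stood at -1.65 without non-metastatic replicate 1, Lyve1 at -1.74 without metastatic replicate 2, and Lce1f at -1.62 without metastatic replicate 1 and at -1.37 without non-metastatic replicate 2. With the mean of a gene's probe sets, values were -1.36 for Scel, -1.63 for Mylk, -1.64 for Lyz1, -1.69 for Lce1f and -0.97 for Map2. Of the 3 probe sets of Lyz1, 2 were lower, at -2.69 and -2.32, and the array's naming marks both as able to bind several transcripts. The other one, not so marked, was dim (4.64) and stood at 0.08 (SE 0.12). The lower value therefore cannot be assigned to Lyz1 alone.

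The 12 genes with the most positive differences were led by Nova1, an RNA-binding splicing factor, at 1.95 (SE 0.22), with 7.04 ± 0.21 against 5.08 ± 0.40. The Wnt modulator Dkk2 stood at 1.70 (SE 0.27), the lipoprotein receptor Vldlr at 1.62 (SE 0.26) and Rpl39l at 1.39 (SE 0.18). Further values were 1.76 (SE 0.73) for Bnip3, a mitochondrial protein induced by low oxygen, 1.72 (SE 0.80) for the cell-surface peptidase Mme, 1.68 (SE 0.68) for the transcription factor Maf, 1.60 (SE 0.37) for Cox7a1 and 1.51 (SE 0.33) for Rgs4. Pfkl, a glycolytic phosphofructokinase, had 1.45 (SE 0.74), Mab21l1 had 1.41 (SE 0.39) and Rps4l had 1.39 (SE 0.38). For Bnip3, Mme and Pfkl the replicates of the metastatic group lay far apart, with SDs of 1.72, 1.90 and 1.75, and for Maf those of both groups did, with SDs of 1.02 and 1.24. Without metastatic replicate 1 the differences were 0.38 for Mme, 0.94 for Maf, 0.96 for Rgs4, 0.76 for Mab21l1, 3.00 for Bnip3 and 2.70 for Pfkl. Without metastatic replicate 2 they were 0.55 for Bnip3, 0.21 for Pfkl and 3.09 for Mme. Maf had 2.55 without non-metastatic replicate 1 and 0.80 without non-metastatic replicate 2, and Rps4l 0.79 without the latter. With the mean of a gene's probe sets, values were 0.98 for Nova1, 0.93 for Maf and 0.93 for Pfkl.

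**Figure D1:**
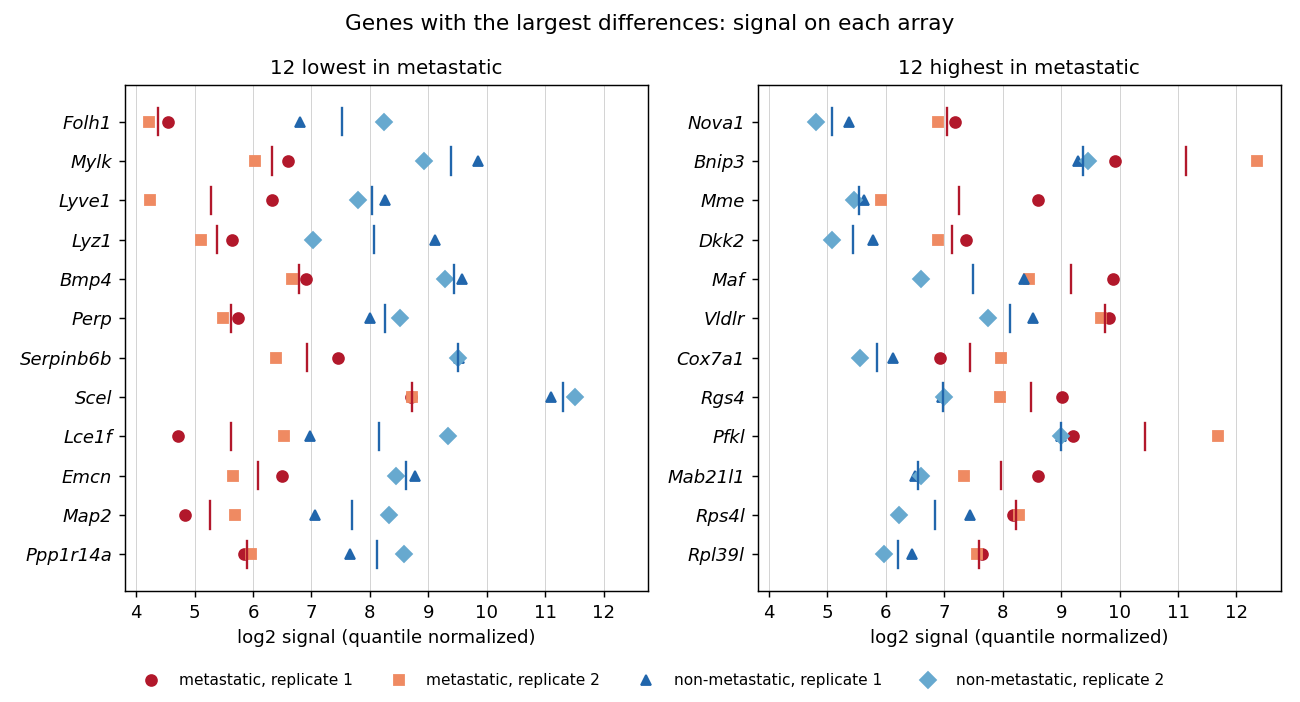
Log2 signal (x axis, quantile normalized) of the 12 genes with the most negative and the 12 with the most positive difference, with 1 symbol per array and a vertical bar at each group's mean (n = 2). Bmp4 sits at 6.90 and 6.66 on the metastatic arrays and at 9.58 and 9.28 on the non-metastatic arrays, while Bnip3 reaches 12.35 on metastatic replicate 2 and 9.92 on metastatic replicate 1.

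None of these differences passed limma with Benjamini-Hochberg adjustment at 0.05 over the 45037 probe sets: 0 probe sets and 0 of 18193 genes were called, and the smallest adjusted p was 0.0863, shared by Bmp4, Actg2 and Scel. At an unadjusted p under 0.05 there were 2731 probe sets, 1328 higher and 1403 lower, where 2251.8 are expected by chance. There were 1219 such genes, 479 higher and 740 lower. The chance value takes probe sets as independent. A split of the same arrays by replicate number gave 2707 probe sets, so the excess is not particular to the split by group. A difference of at least 2-fold was seen for 83 probe sets upward and 208 downward. Both metastatic arrays lay on the same side of both non-metastatic arrays for 34.5% of probe sets, where chance gives 33.3%. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.33. With an intensity trend and robust moderation, limma called 5 probe sets, all lower, among them Bmp4 and Scel (adjusted p = 0.0269) and Perp and Actg2 (adjusted p = 0.0428). The replicate number as a block, a pairing that the labels do not state, gave more calls, counted in the part on processing. Among them were Bmp4 (limma adjusted p = 0.0033), Scel (adjusted p = 0.0058) and Nova1 (adjusted p = 0.0069). Without metastatic replicate 1, limma called 65 probe sets (28 higher, 37 lower) and 34 genes, among them Bmp4, Scel, Actg2, Emcn, Lyve1, Serpinb6b, Bnip3 and Pfkl, and with any other single array left out it called 0 (1348 to 6407 probe sets at an unadjusted p under 0.05).

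Members of the BMP pathway were on balance lower in the metastatic group: 18 of 25 measured genes were lower and 7 higher, with a median log2 difference of -0.10. Bmp4 and Smad6, an inhibitory SMAD that BMP signalling induces, fell. Smad6 had 8.89 ± 0.23 against 9.76 ± 0.02, a difference of -0.88 (SE 0.14). The BMP antagonist Grem1 had a difference of -1.17 (SE 0.30) and the receptor gene Acvrl1 one of -0.47 (SE 0.12), and neither passed. Over all probe sets 0 of the 25 passed, and adjusted over the list alone 2 did, Bmp4 with an adjusted p of 0.000101 and Smad6 with 0.0137 (limma, Benjamini-Hochberg). This list was drawn up knowing that Bmp4 was of interest to the study, and is not independent evidence of its direction. camera called the list lower with the preset correlation (adjusted p = 0.0120), and not with an estimated one (adjusted p = 0.725 with an estimated correlation). Here and below, the p with the preset correlation treats genes as the replicates and does not measure variation between preparations. The list call was lost without metastatic replicate 2 (adjusted p = 0.108) or non-metastatic replicate 1 (adjusted p = 0.482), and the count adjusted over the list alone was 5 without metastatic replicate 1, 3 without metastatic replicate 2 and 1, Bmp4, without either non-metastatic array, each left out alone.

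In the TGF-beta pathway, 9 of 19 genes were higher and 10 lower. Tgfb3 fell, with 8.48 ± 0.16 against 9.16 ± 0.09 (difference -0.68, SE 0.13). The differences of Tgfb2, Tgfb1 and the coreceptor Eng were -1.13 (SE 0.36), 0.32 (SE 0.11) and -0.49 (SE 0.17), and none of the 3 passed. Tgfb2 stood at -0.55 without metastatic replicate 2 and Eng at -0.28 without metastatic replicate 1. No member passed over all probe sets and 1 did adjusted over the list alone (limma adjusted p = 0.0432). The list as a whole was not called (camera adjusted p = 0.636). Without either non-metastatic array no member passed, while 2 passed without metastatic replicate 1 and 6 without metastatic replicate 2.

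Markers of smooth muscle and pericytes, the contractile cells around vessels, had the largest shift of the lists that were lower. Of 14 genes, 10 were lower and 4 higher, with a median of -0.46. Actg2, a smooth muscle actin, fell from 8.85 ± 0.00 in the non-metastatic group to 6.99 ± 0.08 in the metastatic group, a difference of -1.86 (SE 0.11). The smooth muscle myosin gene Myh11 fell by 0.61, Lmod1 of the thin filament by 0.66 and the adhesion molecule Mcam by 1.05 on the log2 scale. Cnn1, named after its value was seen, and Notch3 fell by 1.06 and 0.39. The value of Cnn1 was -0.66 without metastatic replicate 1 and -0.70 without non-metastatic replicate 2. 0 of the 14 passed over all probe sets, and adjusted over the list alone 6 did, all lower (limma, Benjamini-Hochberg). camera called the list lower with the preset correlation (adjusted p = 1.229e-06), and lost it with an estimated one (adjusted p = 0.725 with an estimated correlation). The count of 6 became 3 without metastatic replicate 1, 8 without metastatic replicate 2, 6 without non-metastatic replicate 1 and 1 without non-metastatic replicate 2, and the list call held in each case.

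Among lymphatic endothelial markers, 5 of 13 genes were higher and 8 lower. Lyve1 fell and Pdpn, the gene of the protein used for selection, rose. Lyve1 had 5.27 ± 1.48 against 8.03 ± 0.32, and its values on the metastatic arrays, 6.32 and 4.23, differed from each other by more than a log2 unit. Pdpn had 10.86 ± 0.04 against 10.35 ± 0.00, a difference of 0.51 (SE 0.11). The lymphatic transcription factor gene Prox1 had 3.93 ± 0.27 against 4.07 ± 0.14, and Flt4, the receptor of VEGF-C and VEGF-D, 6.28 ± 0.15 against 6.42 ± 0.27; both differences were smaller than their SE, and they turned to 0.05 for Prox1 without metastatic replicate 2 and to 0.06 for Flt4 without non-metastatic replicate 1. The other probe set of Flt4 had a larger difference, -0.42 (SE 0.17). Prox1 was dim, with mean signals of 3.68 to 4.00 over its 3 probe sets, under the median of all probe sets (5.95). Its small difference therefore does not show that expression was unchanged. The coreceptor Nrp2 differed by 0.71 (SE 0.24) and the transcription factor Foxc2 by -0.61 (SE 0.29), and neither passed. Foxc2 ranged from -0.19 without metastatic replicate 1 to -1.05 without metastatic replicate 2, and Nrp2 had 0.45 without metastatic replicate 2 and 0.47 without non-metastatic replicate 1. Without metastatic replicate 2 Lyve1 stood at -1.74. 0 of the 13 passed over all probe sets, and adjusted over the list alone 2 did (limma adjusted p = 0.0371 for both). The list was not called (camera adjusted p = 0.968). No member passed without either non-metastatic array, and 3 and 4 passed without metastatic replicate 1 and 2.

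Pan and blood endothelial markers were lower for 15 of 23 genes and higher for 8, with a median of -0.13. Emcn fell, with 6.08 ± 0.59 against 8.61 ± 0.23. Ecscr, a surface protein of endothelial cells, had a difference of -1.18 (SE 0.26), Icam2 one of -0.62 (SE 0.15) and the phosphatase gene Ptprb one of -0.52 (SE 0.14), and these did not pass. Icam2 was dim, with 4.45 ± 0.11 against 5.06 ± 0.22. The VEGF receptor gene Kdr had 7.60 ± 0.06 against 7.47 ± 0.04, the junction gene Cdh5 5.52 ± 0.29 against 6.22 ± 0.76 and Pecam1 4.77 ± 0.01 against 5.11 ± 0.35. Cdh5 and Pecam1 had mean signals of 5.87 and 4.94, under the median of all probe sets (5.95). Without non-metastatic replicate 1 the differences of Cdh5 and Pecam1 were -0.16 and -0.10, and without non-metastatic replicate 2 they were -1.24 and -0.59. 0 of the 23 passed over all probe sets, and adjusted over the list alone 1 did (limma adjusted p = 0.00360). camera called the list lower with the preset correlation (adjusted p = 0.00404; adjusted p = 0.725 with an estimated correlation). The call was lost without metastatic replicate 2 (adjusted p = 0.216) or non-metastatic replicate 1 (adjusted p = 0.225). Members past the threshold numbered 6, 1 of them higher, without metastatic replicate 2 and 5 without non-metastatic replicate 2.

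Of the genes of high endothelial venules, the vessels through which lymphocytes enter lymph nodes, 5 of 12 were higher and 7 lower. Selp, which encodes P-selectin, fell from 6.29 ± 0.32 to 5.42 ± 0.15 (difference -0.87, SE 0.18). Its other probe sets stood at -0.26 and -0.21. The sulfotransferase genes Chst2 and Chst4 differed by 0.49 (SE 0.14) and 0.12 (SE 0.11), and the prostaglandin transporter Slco2a1 by -0.33 (SE 0.16). Chst4 had 0.07 without metastatic replicate 2 and 0.08 without non-metastatic replicate 2, and Slco2a1 had -0.52 and -0.14 without non-metastatic replicates 1 and 2. Over all probe sets 0 members passed and adjusted over the list alone 1 did (limma adjusted p = 0.0400), a call that held without non-metastatic replicate 1 and was lost without any of the other 3 arrays. The list was not called (camera adjusted p = 0.968). In the list of VEGF, angiopoietin and apelin signalling, 7 of 18 genes were higher and 11 lower. The mouse Vegfd gene fell by 0.86 on the log2 scale (10.84 ± 0.29 against 11.70 ± 0.09), and Esm1, a proteoglycan of endothelial tip cells, fell by 1.40. Esm1 was dim, with 3.97 ± 0.34 against 5.37 ± 0.61, under the median of all probe sets (5.95). Vegfb and Nrp2 had positive differences of 0.92 (SE 0.25) and 0.71 (SE 0.24) that did not pass, and Vegfb had 0.54 without metastatic replicate 1. Over all probe sets 0 passed, adjusted over the list alone 2 did, and the list was not called (camera adjusted p = 0.984). Its median and mean were below 0 while the sign of camera's test was positive. Without metastatic replicate 1, 5 members passed, 4 of them higher, and Vegfd alone was lower; 3 passed without metastatic replicate 2, Esm1 alone without non-metastatic replicate 2, and 0 without non-metastatic replicate 1.

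Chemokine and cytokine genes were lower for 16 of 24 members and higher for 8, with a median of -0.12 and a mean of -0.43. Cxcl5, a chemokine for neutrophils, fell from 8.88 ± 0.05 to 7.77 ± 0.07 (difference -1.11, SE 0.11). Ccl9 fell from 12.85 ± 0.61 to 10.65 ± 0.62 (difference -2.20, SE 0.38). Tslp and Il7, cytokines that act on lymphocytes and dendritic cells, fell by 0.79 and 0.81 on the log2 scale. Cxcl1 and Lif, named after their values were seen, fell by 1.14 and 0.44, and the 2 probe sets of Lif went in opposite directions; Cxcl1 had -0.74 without metastatic replicate 2. 0 of the 24 passed over all probe sets, and adjusted over the list alone 6 did, all lower (limma, Benjamini-Hochberg). camera called the list lower with the preset correlation (adjusted p = 0.000158; adjusted p = 0.725 with an estimated correlation). Members past the threshold numbered 11 without either metastatic array, 3 without non-metastatic replicate 1 and 4 without non-metastatic replicate 2, and the list call held in each case. All but 2, 1 and 1 of them, without metastatic replicate 2 and without non-metastatic replicates 1 and 2, were lower.

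Genes of adhesion and leukocyte trafficking were lower for 14 of 17 members and higher for 3, with a median of -0.33. Icam1, a ligand of leukocyte integrins, fell from 8.89 ± 0.57 to 7.34 ± 0.20 (difference -1.56, SE 0.27). Selp and Mcam, counted in other lists above, and Icam2 fell, as did the junctional molecule Jam2, named after its value was seen, by 0.57. 0 of the 17 passed over all probe sets, and adjusted over the list alone 5 did (limma, Benjamini-Hochberg). camera called the list lower with the preset correlation (adjusted p = 0.000155; adjusted p = 0.725 with an estimated correlation). No member passed without metastatic replicate 1, and 3 and 1 passed without non-metastatic replicates 1 and 2, while the list call held in each case.

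Among matrix proteases and their inhibitors, 9 of 19 genes were higher and 10 lower. Mmp3, a stromelysin, fell from 7.85 ± 0.36 to 5.67 ± 0.64 (difference -2.18, SE 0.33), and the inhibitor gene Timp3 fell from 13.64 ± 0.23 to 12.13 ± 0.38 (difference -1.51, SE 0.21). Mmp11 had a difference of 0.88 (SE 0.22) and Adamts1 one of -0.59 (SE 0.17), and neither passed; Mmp11 had 0.56 without metastatic replicate 2. Adjusted over the list alone 2 members passed and over all probe sets 0 did (limma adjusted p = 0.00632 for both). The list was not called in either direction (camera adjusted p = 0.494), while limma's fry test for change in either direction gave an adjusted p of 0.0205. The 2 genes passed without any 1 of the 4 arrays, together with 3 others without metastatic replicate 1 and 5 others without metastatic replicate 2. For basement membrane and matrix glycoproteins, 7 of 17 genes were higher and 10 lower. Nid2 fell by 1.48 and Fbln1 rose by 0.98 on the log2 scale, although 1 of the 3 probe sets of Fbln1 was lower. Tnc and Fn1 differed by -1.23 (SE 0.43) and 0.25 (SE 0.13). Tnc had -0.53 without metastatic replicate 1 and -1.94 without metastatic replicate 2, and Fn1 had 0.13 without the latter. Adjusted over the list alone 2 passed (limma adjusted p = 0.0241 for both), over all probe sets 0 did, and the list was not called (camera adjusted p = 0.968). Without non-metastatic replicate 2 no member passed, and without metastatic replicates 1 and 2 there were 4 and 5.

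Genes of hypoxia and glycolysis were higher for 14 of 15 members, with a median of 0.59, a shift that rested on 1 of the metastatic arrays. Bnip3 had 12.35 on metastatic replicate 2 and 9.92 on replicate 1, against 9.29 and 9.45 on the non-metastatic arrays. Pfkl had 11.68 and 9.20, against 8.99 on both. Pfkp and Aldoa, glycolytic enzymes, differed by 0.45 (SE 0.13) and 0.73 (SE 0.21), and Vegfa by 0.79 (SE 0.28). Without metastatic replicate 2, Bnip3 had 0.55, Pfkl 0.21, Aldoa 0.43 and Vegfa 0.36; without metastatic replicate 1, Bnip3 had 3.00, Pfkl 2.70 and Vegfa 1.23. 0 of the 15 passed over all probe sets or adjusted over the list alone (limma, Benjamini-Hochberg), and 3, all higher, had an unadjusted p under 0.05. camera called the list higher with the preset correlation (adjusted p = 0.000158; adjusted p = 0.787 with an estimated correlation). Without metastatic replicate 2 the mean difference was -0.07, the call was lost (adjusted p = 0.967) and 3 members passed, 1 higher and 2 lower. Without metastatic replicate 1, 13 of the 15 passed adjusted over the list alone, all higher.

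**Figure D2:**
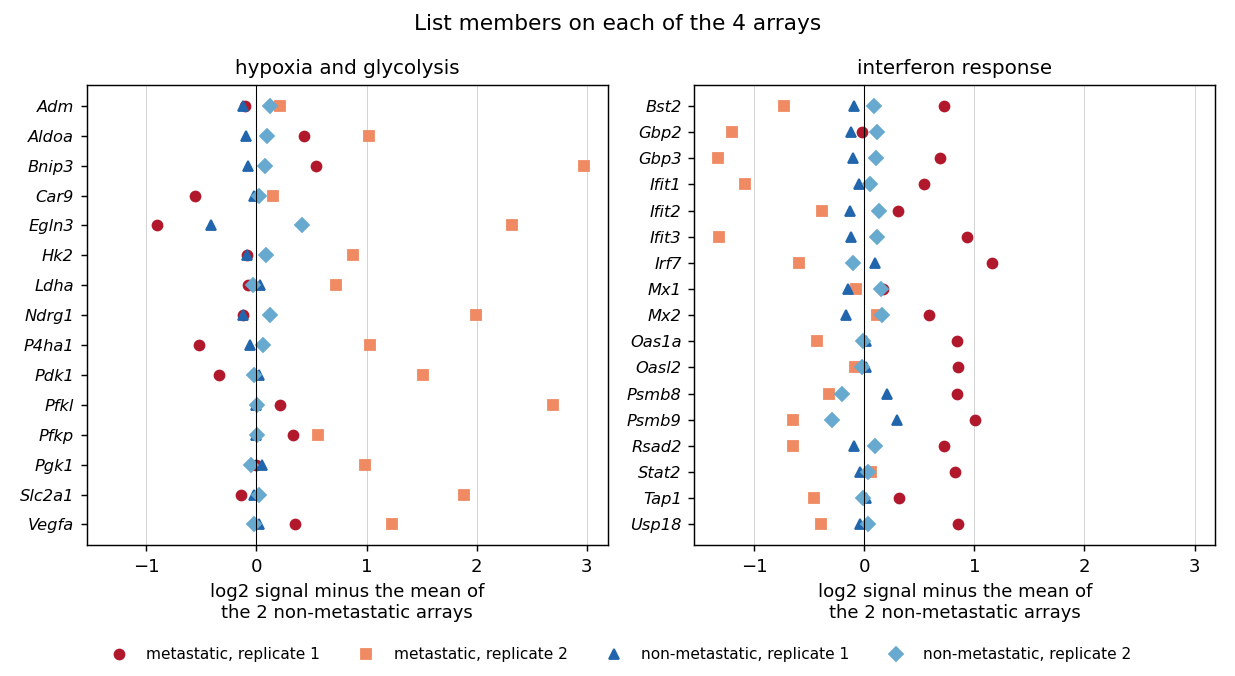
Log2 signal of each list member on each array minus the mean of the 2 non-metastatic arrays (x axis, log2), with 1 symbol per array. All 15 members of the hypoxia and glycolysis list are higher on metastatic replicate 2 than on replicate 1, and all 17 of the interferon response list are lower.

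Cell cycle genes were lower for 21 of 24 members, by a median of -0.18. Rrm2, a subunit of ribonucleotide reductase, had 11.26 ± 0.25 against 12.02 ± 0.02 (difference -0.76, SE 0.15). The replication helicase genes Mcm2 and Mcm4 differed by -0.38 (SE 0.15) and -0.32 (SE 0.13), and the mitotic kinase Cdk1 by -0.31 (SE 0.14). Without metastatic replicate 1 these 3 differences were -0.21, -0.21 and -0.16. 0 of the 24 passed over all probe sets or adjusted over the list alone (limma, Benjamini-Hochberg), and 3, all lower, had an unadjusted p under 0.05. camera called the list lower with the preset correlation (adjusted p = 0.000158; adjusted p = 0.787 with an estimated correlation). Here too the metastatic arrays differed, 23 of 24 genes being higher on replicate 2 than on replicate 1. The call was lost without metastatic replicate 1 (adjusted p = 0.922), and 10 members passed adjusted over the list alone, all lower, without metastatic replicate 2.

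Markers of macrophages and other myeloid cells were lower for 15 of 18 genes, with a median of -0.18. The lysozyme gene Lyz2 had 8.29 and 6.86 on the non-metastatic arrays and 6.06 and 6.16 on the metastatic ones (difference -1.47, SE 0.44). Csf1r, the receptor of colony stimulating factor 1, the Fc receptor gene Fcgr3 and the complement gene C1qc differed by -0.54, -0.52 and -0.66. Without non-metastatic replicate 1 Lyz2, Fcgr3 and C1qc had -0.75, -0.29 and -0.19, and without non-metastatic replicate 2 C1qc had -1.12. Ptprc, which encodes the leukocyte antigen CD45, had 4.15 ± 0.18 against 4.11 ± 0.04, a difference that turned to -0.10 without metastatic replicate 1. Ptprc was dim, under the median of all probe sets (5.95). 0 of the 18 passed over all probe sets or adjusted over the list alone (limma, Benjamini-Hochberg), and 3, all lower, had an unadjusted p under 0.05. camera called the list lower with the preset correlation (adjusted p = 0.00596; adjusted p = 0.734 with an estimated correlation). The call was lost without metastatic replicate 2 (adjusted p = 0.123), without non-metastatic replicate 1 (mean -0.11 against -0.31 with all arrays, adjusted p = 0.338) and in the brighter part of the probe sets (adjusted p = 0.111). Without non-metastatic replicate 2, 4 members passed adjusted over the list alone, all lower. The other 6 lists called lower stand beside this shift in myeloid markers and beside the depletion named for the metastatic preparations.

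Markers of fibroblastic reticular cells and fibroblasts were higher for 8 of 17 genes and lower for 9, with a median of -0.02, and 15 of the 17 had a signal above the median of all probe sets. Postn, a matrix protein of activated fibroblasts, rose by 0.84 (13.43 ± 0.25 against 12.59 ± 0.07) and Il7 fell. The B cell chemokine Cxcl13 had 8.71 ± 1.60 against 10.65 ± 0.25. Its difference of -1.95 (SE 0.69) was -0.81 without metastatic replicate 2 and -3.07 without metastatic replicate 1, where it passed over all probe sets (limma adjusted p = 0.0324). Over all probe sets 0 passed, adjusted over the list alone 2 did (limma adjusted p = 0.0294 and 0.0366), and the list was not called (camera adjusted p = 0.984), its median and mean lying below 0 and camera's sign above. Without metastatic replicate 1 the list was called lower (mean -0.34, adjusted p = 0.0387) and 5 members passed; 4 passed without metastatic replicate 2 and 0 without non-metastatic replicate 1. Markers of other cell types were not called by camera. For dendritic cells and MHC class II genes, 6 of 12 were higher and 6 lower (adjusted p = 0.968), with H2-Eb1 at -0.37 (SE 0.13) and at -0.22 without metastatic replicate 1. For lymphocytes and NK cells, 6 of 11 were higher and 5 lower (adjusted p = 0.968), and 1 of the 11 had a signal above the median of all probe sets. For epithelial cells, 2 of 11 were higher and 9 lower (adjusted p = 0.407). For adipocytes, 5 of 7 were higher and 2 lower (adjusted p = 0.292), with Lpl at 0.69 (SE 0.23) and at 0.33 without metastatic replicate 1. For the dendritic cell list and the lymphocyte list camera's sign was positive and the mean below 0. In these 4 lists 0 members passed over all probe sets or adjusted over the list alone (limma), and at an unadjusted p under 0.05 there were H2-Eb1 and Lpl alone. Without metastatic replicate 2, 3 adipocyte genes passed, all higher, with the list called higher (mean 0.90, adjusted p = 0.00307), and 2 epithelial genes, both lower; 1 epithelial gene, higher, passed without metastatic replicate 1.

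The remaining lists were not called by camera. limma's fry test called 0 of the 24 lists for movement in 1 direction and 3 for change in either direction, the smooth muscle and pericyte list (adjusted p = 0.0205) and 2 others named with their values. The interferon response, the set of genes that interferons induce, was higher for 10 of 17 members and lower for 7 (camera adjusted p = 0.539), with 0 members past either threshold or at an unadjusted p under 0.05 (limma). Its direction followed the metastatic array used: without metastatic replicate 1 it was called lower (mean -0.56, camera adjusted p = 4.01e-09, 10 members lower), and without metastatic replicate 2 it was called higher (mean 0.66, camera adjusted p = 3.332e-11, 13 members higher). The Notch pathway had 5 of 14 genes higher and 9 lower (camera adjusted p = 0.211), with Hes1, a target of Notch signalling, at -0.30 (SE 0.12; -0.20 without metastatic replicate 2), and 0 members passed (2 at an unadjusted p under 0.05), against 3 without metastatic replicate 1. Prostaglandin metabolism and receptors had 7 of 13 higher and 6 lower (camera adjusted p = 0.539), with the cyclooxygenase gene Ptgs2 at -1.04 (SE 0.34) and the receptor gene Ptger4 at -0.81 (SE 0.23). Ptgs2 had -0.52 without metastatic replicate 1 and -1.56 without metastatic replicate 2, and Ptger4 had -0.54 without non-metastatic replicate 1. The list's median was positive and its mean negative, and 0 members passed (2 at an unadjusted p under 0.05), against 4 without metastatic replicate 2. Of the regulators of endothelial-mesenchymal transition, 5 of 12 were higher and 7 lower (camera adjusted p = 0.539). The fibroblast growth factor receptor Fgfr1 rose, with 10.57 ± 0.07 against 9.94 ± 0.05, and Klf4 and Snai1 differed by -0.52 and 0.37 without passing, with -0.32 for Klf4 without non-metastatic replicate 1 and 0.24 for Snai1 without non-metastatic replicate 2. Adjusted over the list alone 1 member passed (limma adjusted p = 0.0184), and fry's test for change in either direction gave an adjusted p of 0.0374. Without metastatic replicates 1 and 2, 4 and 5 members passed, and without either non-metastatic array 0 did. Of the stress and immediate early genes, 4 of 16 were higher and 12 lower (camera adjusted p = 0.153). Ddit3, a transcription factor of the unfolded protein response, rose by 0.68, and the phosphatase gene Dusp1 fell by 0.64 (limma adjusted p = 0.0147 for both, adjusted over the list alone), with Jun at -0.40 (SE 0.12). The other probe set of Ddit3 stood at 0.145 (SE 0.244). Without either non-metastatic array neither passed; without metastatic replicate 1, 4 members passed and the list was called lower (mean -0.26, camera adjusted p = 0.00873), as it was with the mean of all probe sets of a gene (camera adjusted p = 0.0487).

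**Figure D3:**
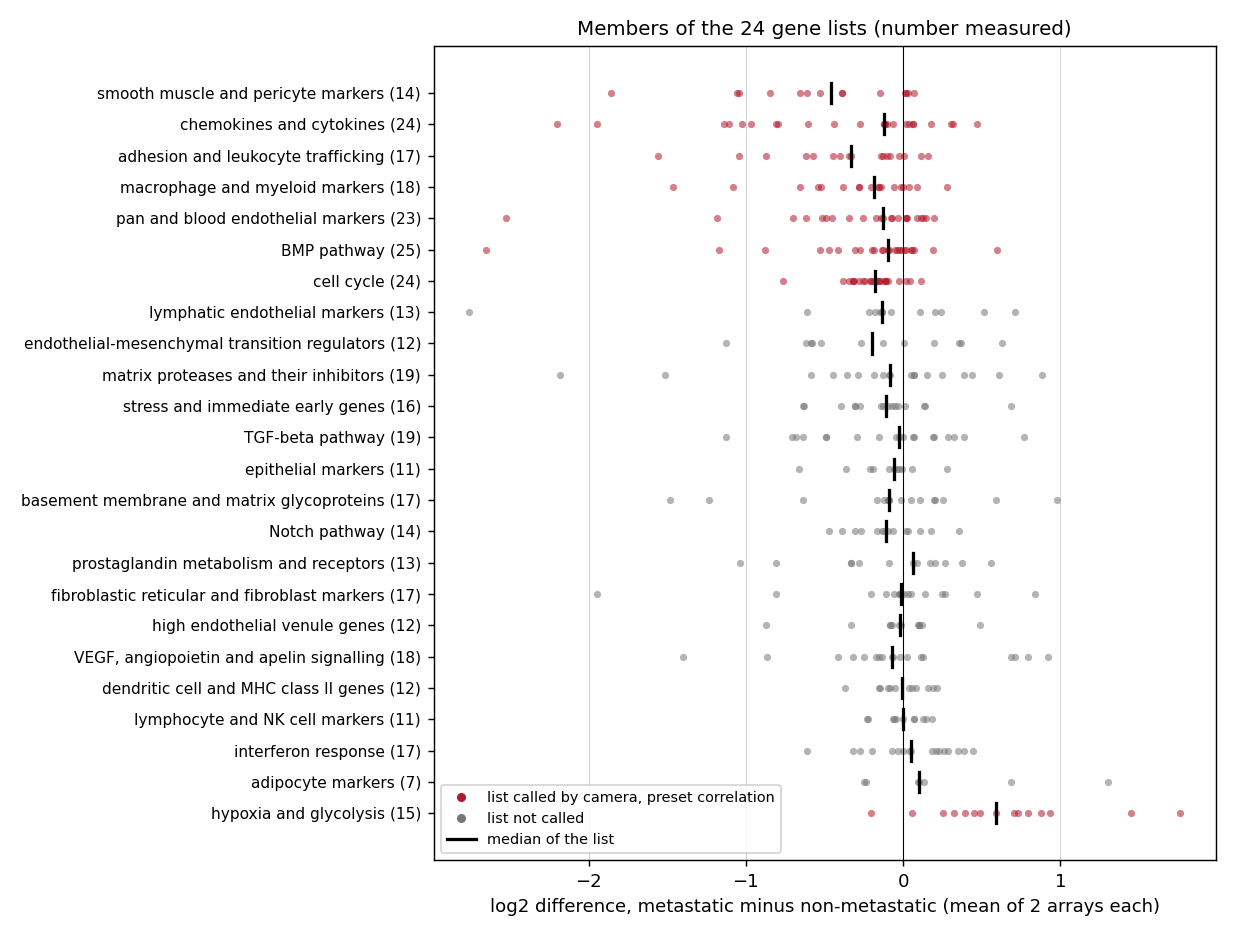
Log2 difference, metastatic minus non-metastatic (x axis), of each measured member of the 24 gene lists, with a point per gene, a black bar at the list's median and red for the 8 lists that camera called with the preset correlation. The smooth muscle and pericyte list has the lowest median, -0.46, and the hypoxia and glycolysis list the highest, 0.59. None of the 8 calls held with an estimated correlation, which leaves the test 2 degrees of freedom. With the preset correlation the test does not measure variation between preparations.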

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

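The tests of degraded RNA, of the normalization and of mural cells as the whole difference were chosen after the results they concern were seen. The other tests in this part were set down beforehand.

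A signal in control probe sets, which are outside the main measurement, differed with the group. The 9 probe sets of the E. coli and P1 hybridization controls, spiked into the labelled sample, were higher on the metastatic arrays by a mean of 0.246 log2 units, between 0.130 and 0.324, and all 9 were higher on both metastatic arrays. The 12 probe sets of the poly-A controls, spiked into the RNA, differed by -0.04.

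The first pattern is the lower Bmp4 signal, -2.65 log2 units in the metastatic group. A smaller share of endothelial cells would lower their markers together. The 13 blood and pan endothelial markers used in this test had a median of -0.172 (95% bootstrap interval -0.492 to 0.0228). The 11 fibroblast markers used had 0.0289 (-0.107 to 0.250). Both lie above the limit of -1, which argues against a broad loss of either as the whole of the Bmp4 difference. The intervals are over genes and hold no variation between arrays. Dim markers and the lymphatic list were not part of the test. camera called the full endothelial list lower with the preset correlation (adjusted p = 0.00404), so a smaller loss of endothelial cells stays open. The 10 smooth muscle and pericyte markers had a median of -0.524 with an interval from -1.05 to -0.149 that includes the limit of -1. A smaller share of mural cells may therefore contribute. As the whole of the Bmp4 difference it would need a median near -2.34, below the lower end of -1.05. Single members ran from -1.86 for Actg2 to 0.0710. Mylk and Ppp1r14a, outside the list, had -3.07 and -2.23, so the median does not speak for every kind of mural cell. A lower Bmp4 signal within the selected cells stays open, as does a loss of 1 kind of endothelial cell, since Emcn differed by -2.53. VEGF-D from the tumour, node enlargement and any depletion went with the group and cannot be told apart from it.

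The second pattern is the lower signal of macrophage and myeloid markers in the metastatic group, a mean of -0.31 over the list that was -0.11 (camera adjusted p = 0.338) without non-metastatic replicate 1; lymphocyte and dendritic cell markers went both ways, with 6 of 11 and 6 of 12 higher. The mice were immunodeficient, and 1 of the 11 lymphocyte markers had a signal above the median of all probe sets. The lymphocyte list could therefore show little of a depletion. If leukocytes were depleted in the metastatic preparations alone, as the sorting label reads, the myeloid markers would be lower. The limit set for the test was -0.3. The 7 macrophage and myeloid markers used had a median of -0.278 (95% bootstrap interval -0.540 to -0.000999), on both sides of that limit. Depletion, if it differed, went with the group, so it and the tumour type cannot be told apart here.

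The third pattern is the higher signal of hypoxia and glycolysis genes on metastatic replicate 2 than on metastatic replicate 1, a median of 0.99 log2 units. The 3' minus 5' signal of the Gapdh and beta-actin controls differed between the 2 arrays by at most 0.0329 log2 units, against a limit of 0.5, so degraded RNA is unlikely to account for it. The shift after quantile normalization was 0.968 of that in the deposited values, which argues against the normalization. The labels name no condition that differs between the 2 arrays, and no biological explanation was tested; different culture of the preparations stays open.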

How the results depend on the processing

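The alternatives were set before the data were examined, except the counts of list members without each array; unless an array was left out, the cause was not tested. With the deposited values, centred medians, the brighter probe sets or a fold of at least 2, limma called 0 probe sets and 0 genes (1752 to 2731 and 860 to 1219 at an unadjusted p under 0.05), as it did for genes with the mean of all probe sets. Trend and robust settings gave 5 probe sets and 4 genes, all lower. The replicate number as a block gave 145 probe sets (25 higher, 120 lower) and 93 genes (14 and 79), with 8 lists. The labels do not say that the numbers pair the samples. Deviations of same-numbered arrays from their group means correlated at 0.248 across the probe sets. With 2 arrays per group the deviations mirror each other, so this is a single value and no test of pairing. Leaving out each array gave 0 to 65 probe sets, 0 to 34 genes and 5 to 10 called lists, against 8.

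The estimated correlation left 0 lists called, with 2 degrees of freedom for the test. For adhesion the estimate was -0.0442, below the preset 0.01, and camera's unadjusted p still went from 1.29e-05 to 0.0424. Loss of a call with this setting is therefore not a measure of correlation alone. The other called lists had estimates above the preset. These were 0.044 for chemokines, 0.0668 for BMP, 0.0703 for pan and blood endothelial and 0.195 for macrophage. For smooth muscle and pericytes, cell cycle, and hypoxia and glycolysis they were 0.284, 0.798 and 0.963. In those lists correlated members can have contributed to the loss. The trend and robust settings do not enter the list test and repeat its main result. Over the 11 alternatives of each called list, adjusted p ran from 1.7e-09 to 0.725 for smooth muscle and pericytes, 2.389e-06 to 0.725 for adhesion and 5.158e-07 to 0.725 for chemokines, lists whose call was lost with the estimated correlation alone. It ran from 3.329e-05 to 0.725 for BMP, 6.482e-07 to 0.725 for pan and blood endothelial, 7.932e-08 to 0.734 for macrophage, 2.005e-09 to 0.922 for cell cycle and 2.316e-20 to 0.967 for hypoxia and glycolysis.

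Mean differences that changed sign were those of lymphocyte markers with centred medians (6.54e-06), and of high endothelial venule genes (0.0544) and VEGF signalling (0.0667) in the brighter probe sets. Leaving out each array, means crossed 0 for high endothelial venules (-0.0987 to 0.00180), fibroblasts (-0.340 to 0.205), dendritic cells (-0.0315 to 0.00136), lymphocytes (-0.0284 to 0.0205), epithelial (-0.262 to 0.0208) and adipocyte markers (-0.380 to 0.901), VEGF signalling (-0.0895 to 0.0368), basement membrane (-0.243 to 0.0482), interferon response (-0.562 to 0.665), and hypoxia and glycolysis (-0.0673 to 1.35). So did Flt4 (-0.325 to 0.0571), Prox1 (-0.334 to 0.0547) and Ptprc (-0.0950 to 0.166; -0.0288 with the mean of its probe sets). Of 563 other values for 96 named genes, 533 kept direction and side of the threshold and 29 newly passed. As no gene passed in the main fit, keeping its side meant failing again, and no call could be lost. The trend, block and brighter-probe-set settings leave the difference itself unchanged, so direction could not turn there. Without detection calls, low signals such as those of Prox1 and Ptprc cannot be set against background.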

Other observations

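The mesothelial list was chosen after the data were seen. The replicates of the metastatic group differed from each other in whole groups of genes. On metastatic replicate 2 all 17 measured interferon response genes were lower than on replicate 1, with a median difference of -1.24 log2 units, and Ifit3 had 10.68 against 12.93 and Gbp3 8.29 against 10.30. Adipocyte markers were higher for 1 of 7 genes, with a median of -0.69; Adipoq, which encodes adiponectin, had 4.52 against 9.04, and Pparg, a transcription factor of fat cells, 8.52 against 10.68. Fibroblast markers were higher for 5 of 17 genes, with a median of -0.31. Hypoxia and glycolysis genes were higher for 15 of 15 genes, with a median of 0.99, and cell cycle genes for 23 of 24, with a median of 0.36. Against 10000 random lists of the same size and signal, these 5 medians lay at percentiles of 0, 0, 0, 100 and 100, which describes these 2 arrays and is no test of a condition. Chemokines and cytokines, a list called lower between the groups, had a median of -0.20 here (9 of 24 higher on replicate 2, percentile 0.07), against -0.12 between the groups, and basement membrane and TGF-beta pathway genes had 0.23 and 0.19 (percentiles 99.82 and 99.6). The genes named here were chosen by their values.

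Between the non-metastatic arrays the shift of the same lists was smaller for hypoxia and glycolysis (median 0.05, replicate 2 minus replicate 1) and for the interferon response (0.10). The macrophage and myeloid markers differed, with a median of -0.23 and 4 of 18 genes higher on replicate 2, at percentile 0 of the random lists. Lyz2 had 8.29 on replicate 1 and 6.86 on replicate 2, and C1qa 6.69 and 4.88. Of the other lists called lower between the groups, BMP pathway genes had a median of -0.13 here (6 of 25 higher on replicate 2, percentile 0.04), against -0.10 between the groups, and pan and blood endothelial markers -0.11 (5 of 23, percentile 0.36). Prostaglandin and basement membrane genes were shifted upward, with 0.17 and 0.11 (percentiles 99.76 and 99.6).

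Across all 45037 probe sets, the 2 metastatic arrays correlated at 0.991, with 606 probe sets more than 1 log2 unit apart, and the 2 non-metastatic arrays at 0.995, with 228. The 4 pairs of arrays from different groups correlated at 0.991 to 0.993, with 426, 462, 623 and 639 such probe sets. Those with 426 and 462 were the same-numbered arrays, and both lie under the 606 of the metastatic arrays. Genes, here probe sets, are not independent replicates. The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The split by group gave 291 probe sets with a difference of at least 2-fold, and the highest of the other splits, by replicate number, gave 202; limma called 0 probe sets in each split, with 2731, 2707 and 753 at an unadjusted p under 0.05 for the split by group, by number and the third one.

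Scel, Perp and Lce1f, genes best known from epithelia, were among the largest negative differences, while the epithelial markers as a list were not called. Of 12 mesothelial markers, 11 were measured, 8 lower and 3 higher, with a median of -0.13 (camera p = 0.149, and p = 0.270 with an estimated correlation), and 4 of the 11 had a signal above the median of all probe sets. Those with an unadjusted p under 0.05 went both ways: Nkain4 at -0.63 (SE 0.11), Wt1 at 1.00 (SE 0.24) and Cldn15 at 0.64 (SE 0.26).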
